A study of Solanum lycopersicum with 18 samples.

How the data were processed

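RNA was profiled in fruits of tomato (Solanum lycopersicum) of 3 genotypes at 2 ages, with 3 libraries in each of the 6 groups and 18 libraries in all. Per the labels, plants grew in a glasshouse with 16 h of light at 26°C and 8 h of dark at 20°C, and fruits were picked at ages given as 35 and 45 DAP, sliced and frozen. Total RNA was extracted with SDS and phenol, cleaned on columns and made into standard Illumina libraries, per the labels' protocols. The labels call the libraries triplicates and do not say whether the 3 of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be partly technical.

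The authors deposited one table of RPKM values (reads scaled by gene length and by the library's read total) for 35802 gene identifiers of the Solyc series, with one column per library named by its title, and the file headers give no other unit. CASAVA 1.8.1 and Bowtie2, whose version is not stated, are named in the submitters' processing notes, with no role or order. The genome build, the annotation and the counting program are not given in the sources used here. Groups and replicate numbers were taken from the titles, and 0 columns were left without a sample. The labels do not say what a replicate number marks. Libraries were checked for pairing by the correlation of their deviations from the group means. In 1 of 15 pairs of groups, TF18 and the wild type at 35 DAP, all 3 same-numbered pairs lay over 0.1 (0.284 to 0.47), the bound set for pairing, and 5 of the 6 differently numbered pairs were negative. The numbers are treated as possible pairs in that comparison alone, and this rests on the data only. Libraries of different numbers passed the same bound elsewhere. Wild-type replicates 1, 2 and 3 of 35 DAP correlated at 0.392, 0.18 and 0.257 with rin replicates 3, 1 and 2 of 35 DAP. Passing the bound is thus weak evidence of pairing.

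The RPKM values keep whole steps. For each of the 28612 genes with a value above 0 the reads and the coding length were solved from these steps, with a tolerance of 0.02 reads, and 100.0% of the values above 0 came out as whole reads. The 18 read totals that the values imply lay within 0.0037 of whole numbers with lengths taken as multiples of 3 bases, which is why lengths are called coding lengths (median 957 bases). On simulated data the procedure returned every read count of 2874 genes and all 18 totals exactly. Read totals ranged from 5740900 to 17334324 per library. The deposited scale divides by these totals, so values are relative to all reads counted in a library and a change in total RNA per fruit cannot be seen in them. Ratios of pooled reads are given with exact conditional 95% intervals. These cover counting error only, because reads are pooled over the 3 libraries of a group and the spread between libraries is left out. The reads also carry no molecular identifiers.

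Tests were run on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3. One model held the means of the 6 groups over all 18 libraries, with variances moderated along a trend in mean expression, and two-sided p-values were adjusted over genes by the Benjamini-Hochberg method. Genes with at least 1 RPKM in at least 3 libraries were tested, which left 20658. A gene is called higher or lower, or is said to have risen or fallen, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(RPKM + 1) scale and understate the change of low genes. The model has 8 pairwise comparisons and 2 contrasts that test whether the change from 35 to 45 DAP in a genotype differs from that of the wild type. In simulated data for rin against wild type at 45 DAP over 20658 genes, 76% of 100 genes changed by 1.5 on the log2 scale and 94% of 100 changed by 3 were recovered, and 7 unchanged genes were called. The changed genes were drawn only from those with a mean log2 value over 3 in the wild type at 45 DAP. Noise was normal and independent between genes, so the recovery does not cover lower genes or correlated ones. Shares of summed RPKM were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Other computations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

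The design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the largest rises and falls among called genes whose 3 libraries of one group all lie above the 3 of the other and whose mean is at least 10 RPKM in one group. The files do not pair identifiers with gene names, and 0 of the 35802 identifiers matched the RefSeq gene table of assembly SLM_r2.1 that was at hand. Genes are therefore given by identifier, at most 2 that rose and 2 that fell in each of the 3 main comparisons in place of the 5 each that the rule allows. For the same reason no function is given as a result, and the 13 gene lists and 14 keyword lists fixed in advance were not used in any test. None of their entries could be checked, and those mentioned below are marked as unchecked. Values of RIN, FUL1 and FUL2 are not reported here, so the genotype labels were not checked on their target genes.

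Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter, a filter at 5 RPKM, rescaling by trimmed means of log ratios (TMM-type, with 30% of log ratios and 5% of abundances trimmed at each end), quantile normalization, the replicate number as a block, only the groups compared in the fit, library weights, and each library left out in turn. Added after seeing the data were voom on the recovered reads, libraries thinned to the depth of the shallowest, and a fit of only TF18 and the wild type at 35 DAP with the replicate number as a block.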

Results

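Gene expression was measured by RNA sequencing in tomato fruits of the wild type (cultivar Ailsa Craig), the rin mutant, and TF18, a transgenic line in which FUL1 and FUL2 are suppressed. RIN, FUL1 and FUL2 are MADS-box transcription factors of fruit ripening. Fruits were taken at 35 DAP, when the wild type was green, and at 45 DAP, when it was pink, with 3 libraries per group. Read totals ran from 5740900 reads in wild-type replicate 2 of 45 DAP to 17334324 in wild-type replicate 1 of 35 DAP. The wild-type libraries of 45 DAP had the lowest mean depth of the 6 groups, 8.03 M reads ± 2.36 (SD, n = 3), against 16.5 M ± 1.04 (SD, n = 3) at 35 DAP. They also held fewer genes at 1 RPKM or more, 15494 ± 670 (SD, n = 3) against 18848 ± 139 (SD, n = 3). With all libraries thinned to one depth, genes with a read numbered 19741 ± 620 (SD, n = 3) and 22584 ± 134 (SD, n = 3). Replicates differed by more than sampling noise, with a chi-square per gene of 24.2 to 166 over the 18 pairs.

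The first comparison asked what changes between the green and the pink fruit of the wild type. Genes that fell were the larger group on the deposited scale, with 7072 lower and 1557 higher at 45 DAP among 20658 tested, and 946 of the falls and 264 of the rises were at least 8-fold on the fitted scale. Solyc10g080210 rose from 3.42 RPKM ± 0.80 (SD, n = 3) to 15470 ± 10830 (SD, n = 3), a log2 fold change of 11.56 (SE 0.39, limma adjusted p = 2.2e-11). Solyc08g066240 rose from 1.32 RPKM ± 0.36 (SD, n = 3) to 6866 ± 977 (SD, n = 3), a log2 fold change of 11.54 (SE 0.26, limma adjusted p = 1.4e-13). Solyc09g090150 fell from 5003 RPKM ± 2255 (SD, n = 3) to 23.5 ± 31.4 (SD, n = 3), a log2 fold change of -8.50 (SE 2.24, limma adjusted p = 0.0042). Solyc03g005580 fell from 2958 RPKM ± 2245 (SD, n = 3) to 7.02 ± 5.98 (SD, n = 3), a log2 fold change of -8.45 (SE 1.88, limma adjusted p = 0.0013). Both of these varied widely between replicates, and in TF18 a single library of each age held nearly all of their reads.

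The balance of rises and falls in the wild type depended on the scaling. The median log2 fold change of all genes tested was -0.58 as deposited, -0.15 with TMM-type scaling and 0.08 with quantile normalization. Calls numbered 3651 higher and 4926 lower with TMM-type scaling, and 3085 higher and 3196 lower with quantile normalization. At the same time the 100 most abundant genes of each library held 40.1% ± 5.36 (SD, n = 3) of the summed RPKM at 45 DAP and 31.4% ± 2.11 (SD, n = 3) at 35 DAP. With a pseudocount of 5 RPKM, 3711 genes were called lower.

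**Figure D1:**
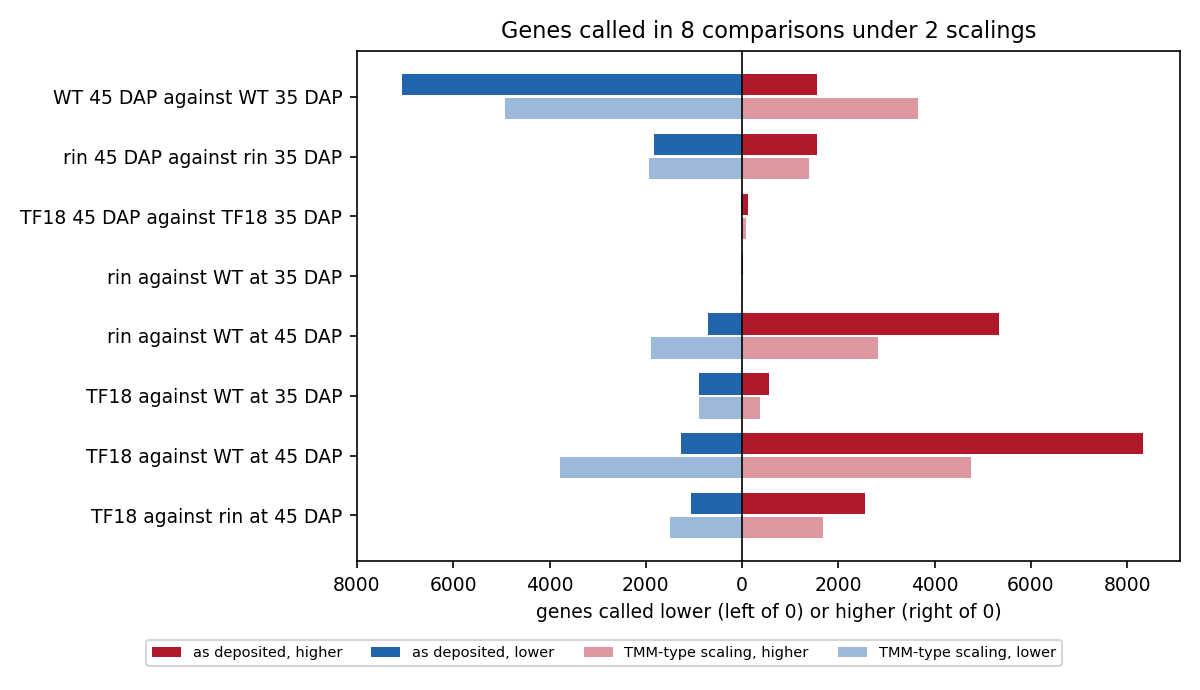
Genes called higher (right of 0) and lower (left of 0) in the 8 pairwise comparisons, as deposited (dark bars) and with TMM-type scaling (light bars). The wild-type interval had 7072 falls as deposited and 4926 after rescaling, while rin against wild type at 35 DAP had 12 higher and 7 lower genes as deposited.

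The same interval was then followed in rin, whose fruits do not ripen normally. Between 35 and 45 DAP, 1547 genes rose and 1827 fell in rin, with a median log2 fold change of 0.04 over all genes. With a pseudocount of 5 RPKM 982 rose and 933 fell. Of the 1557 genes that rose in the wild type, 566 also rose in rin, where independent lists would share 117, and 10 fell. Of the 7072 that fell in the wild type, 1644 also fell in rin, where independent lists would share 625, and 110 rose. With TMM-type scaling 716 of 3651 rises and 1593 of 4926 falls were shared. The genes that rose in the wild type had a median log2 fold change of 1.62 there and 0.80 in rin, and those that fell had -1.75 there and -0.48 in rin. Because these genes were chosen on the wild-type libraries, their wild-type medians are not independent of the choice. The test of the difference itself called 5408 genes, 4794 with a higher and 614 with a lower change in rin than in the wild type. These included 516 of the wild-type rises, smaller in rin, and 3674 of the wild-type falls, smaller in rin, and with TMM-type scaling 1631 rises and 1631 falls. The wild-type libraries used for the choice also enter this difference, so a smaller change in rin is partly favoured by the choice. With TMM-type scaling the difference was called higher for 2157 and lower for 1929 genes, and with quantile normalization for 1169 and 1192.

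In TF18 few genes passed the test over this interval, 117 higher and 30 lower, although 2008 genes had an unadjusted limma p under 0.05. If no gene changed, a share of 0.05 of the 20658 tested would be expected there, so part of the 2008 may be chance. Quantile normalization gave 73 higher and 38 lower, and library weights gave 646 and 211. Of the 1557 wild-type rises, 11 rose in TF18, where independent lists would share 8.8, and 14 of the 7072 wild-type falls fell there, where they would share 10.3. With library weights 92 rises and 114 falls were shared, where independent lists would share 50.3 and 67.4. Quantile normalization gave 13 rises and 15 falls (10.9 and 5.9 from independent lists). A pseudocount of 5 RPKM gave 6 and 13 (4.2 and 5.2), and TMM-type scaling 12 and 10 (14.5 and 7.2). The wild-type rises had a median log2 fold change of 0.11 in TF18 and the wild-type falls had 0.07. The change differed from that of the wild type for 8180 genes, 6934 with a higher and 1246 with a lower change in TF18. Among the wild-type rises 1100 were called smaller in TF18, and among the wild-type falls 5993 were, and with TMM-type scaling 3042 rises and 3880 falls were. As in rin, a smaller change is partly favoured by the choice of genes on the wild-type libraries. With TMM-type scaling the difference was called higher for 4426 and lower for 3498 genes, and with quantile normalization for 2617 and 2888. Without TF18 replicate 2 of 35 DAP the interval had 65 higher and 13 lower genes, without TF18 replicate 3 of 35 DAP it had 66 lower, and without TF18 replicate 2 of 45 DAP it had 18 lower. The shared counts in TF18 moved from 5 to 20 rises and from 5 to 41 falls as single libraries were left out.

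The share of the summed RPKM held by these genes was followed in each library on the deposited scale. The genes were chosen on the wild-type libraries, so the wild-type change in share, and its larger size than in rin and TF18, are partly fixed by the choice and are given as a description. Wild-type rises held 11.4% ± 0.47 (SD, n = 3) in the wild type at 35 DAP and 47.4% ± 6.49 (SD, n = 3) at 45 DAP. In rin they held 12.9% ± 0.71 (SD, n = 3) and 22.9% ± 1.70 (SD, n = 3), and in TF18 13.2% ± 1.10 (SD, n = 3) and 14.6% ± 0.57 (SD, n = 3). Wild-type falls went from 37.4% ± 1.95 (SD, n = 3) to 5.28% ± 0.07 (SD, n = 3) in the wild type and from 35.8% ± 2.52 (SD, n = 3) to 17.2% ± 2.59 (SD, n = 3) in rin. In TF18 they held 30.5% ± 1.93 (SD, n = 3) and 27.8% ± 2.45 (SD, n = 3), a difference within the spread of the libraries (two-sided exact permutation p = 0.2). The other 3 differences between ages in rin and TF18 had an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give, so none of them can pass 0.05 by this test.

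**Figure D2:**
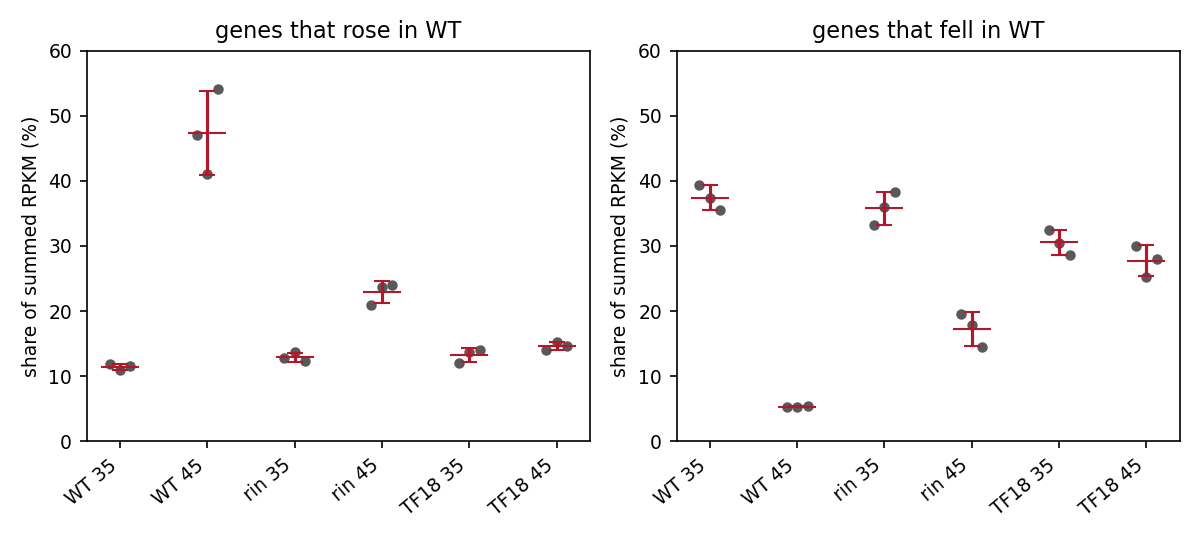
Share of the summed RPKM (percent) held by the 1557 genes that rose (left) and the 7072 that fell (right) in the wild type between 35 and 45 DAP. Dots are libraries, and bars are the mean and SD of 3. The rises reach 47.4% in the wild type at 45 DAP, 22.9% in rin and 14.6% in TF18.

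The genotypes were next compared at 35 DAP, before the wild type ripens. Only 12 genes were higher and 7 lower in rin than in the wild type by limma, and 527 had an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 20658 tested would be expected there, which is more than 527. With only the compared groups in the fit, 6 genes were higher and 1 was lower. TF18 differed more from the wild type at this age, with 560 genes higher and 904 lower. That count rested in part on single libraries. Without TF18 replicate 2 it was 269 higher and 402 lower, without wild-type replicate 1 it was 313 and 475, and without TF18 replicate 3 the lower genes were 593. Library weights gave 976 higher and 1612 lower, a pseudocount of 5 RPKM gave 312 and 469, and a filter at 5 RPKM gave 560 lower.

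At 45 DAP, where the question was which changes of ripening are missing in the mutant, 5344 genes were higher and 707 lower in rin than in the wild type. The genes that did not rise are visible one by one. Solyc10g080210 was at 2.45 RPKM ± 1.66 (SD, n = 3) in rin against 15470 ± 10830 (SD, n = 3) in the wild type, a log2 fold change of -12.00 (SE 0.39, limma adjusted p = 1.5e-11). Solyc08g066240 was at 1.53 RPKM ± 1.12 (SD, n = 3) against 6866 ± 977 (SD, n = 3), a log2 fold change of -11.50 (SE 0.26, limma adjusted p = 1.5e-13). Solyc05g051850 was higher in rin, at 2164 RPKM ± 758 (SD, n = 3) against 10.5 ± 3.41 (SD, n = 3), a log2 fold change of 7.53 (SE 0.36, limma adjusted p = 1.7e-09). It fell in the wild type between the ages and rose in rin, from 385 RPKM ± 144 (SD, n = 3). Solyc03g123830 was at 248 RPKM ± 72.7 (SD, n = 3) in rin against 1.89 ± 1.01 (SD, n = 3), a log2 fold change of 6.45 (SE 0.37, limma adjusted p = 1.3e-08). The median log2 fold change of all genes was 0.49. With TMM-type scaling 2832 genes were higher and 1896 lower (median 0.07), and with quantile normalization 1659 and 1367 (median -0.04).

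TF18 at 45 DAP had 8323 genes higher and 1278 lower than the wild type. Solyc10g080210 had 4 reads over the 3 TF18 libraries against 495401 in the wild type, a log2 fold change of -13.59 (SE 0.39, limma adjusted p = 2.3e-12) and a ratio of pooled reads of 183700 (95% counting interval 71740 to 674100). Solyc08g066240 had 1 read in TF18 against 224112 (ratio 332400, 95% counting interval 59650 to 13130000), with a log2 fold change of -12.71 (SE 0.26, limma adjusted p = 3.3e-14). Solyc07g007260 was at 642 RPKM ± 486 (SD, n = 3) in TF18 against 1.19 ± 2.06 (SD, n = 3) in the wild type, where it had 7 reads, a log2 fold change of 8.35 (SE 0.77, limma adjusted p = 4.4e-07). Solyc09g008670 was at 257 RPKM ± 147 (SD, n = 3) in TF18 and had 3 reads in the wild type, a log2 fold change of 7.74 (SE 1.17, limma adjusted p = 4.1e-05), with a ratio of pooled reads of 3437 (95% counting interval 1176 to 16670). Both of these higher genes were also called higher in TF18 than in the wild type at 35 DAP. There the log2 fold changes were 4.62 (SE 0.77, limma adjusted p = 0.0021) for Solyc07g007260 and 4.93 (SE 1.17, limma adjusted p = 0.016) for Solyc09g008670. The latter ranged from 5.42 to 633 RPKM over the TF18 libraries of 35 DAP. At 45 DAP the median log2 fold change of all genes was 0.75. TMM-type scaling gave 4760 higher and 3773 lower (median 0.10), and quantile normalization 3254 and 2803 (median -0.02).

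**Figure D3:**
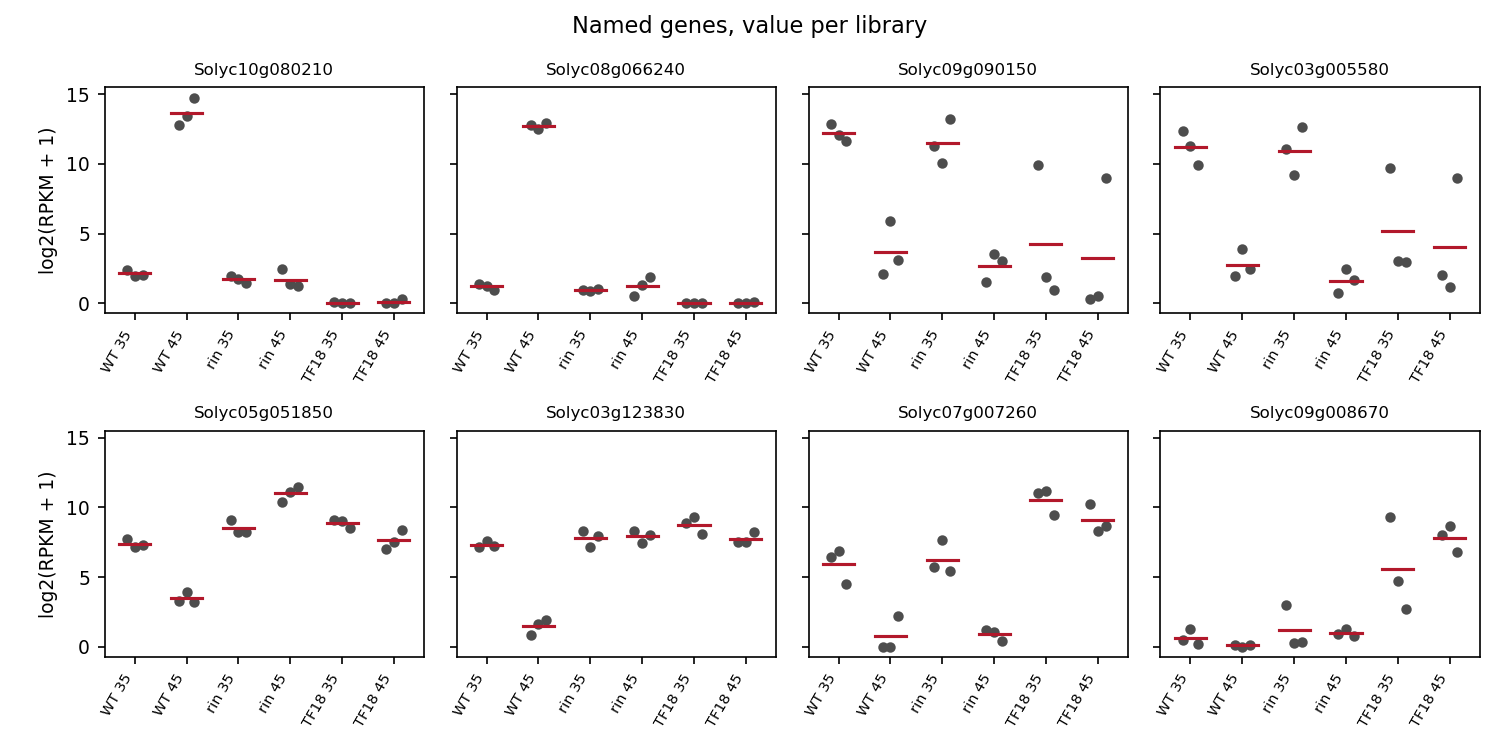
Expression of the 8 genes named by the rule, as log2(RPKM + 1) in each library (dots) with the mean of the 3 (bars), by genotype and age in DAP. Solyc10g080210 and Solyc08g066240 are high in the wild type at 45 DAP and low in the other 5 groups, and Solyc09g090150 and Solyc03g005580 are high in 1 of 3 TF18 libraries at each age.

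Both genotypes were set side by side at 45 DAP. Of the genes higher than in the wild type, 4436 were higher in both, which is 83% of those higher in rin, and independent lists would share 2153. Of those lower, 550 were lower in both, which is 77.8% of those lower in rin, where independent lists would share 44. Opposite directions were called for 19 genes. Across genes, which are not independent replicates, the fold changes had a correlation of 0.733 and a covariance of 1.099. Unchanged groups were simulated 50 times from the wild-type means of 45 DAP plus residuals drawn from the 18 libraries. Both were set against the same simulated wild type, so the error of the real wild-type libraries was not kept. The simulated groups gave correlations from -0.053 to 0.82 (mean 0.476), so the observed correlation lies within the simulated range of no change. Their covariances ran from -0.005 to 0.196 (mean 0.072), below the observed one by 1.027 on average. In fits of the simulated libraries alone, 0 genes were called in both. The 3 wild-type libraries cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls. TMM-type scaling gave 2094 genes higher in both and 1636 lower in both, and quantile normalization 1098 and 1078.

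**Figure D4:**
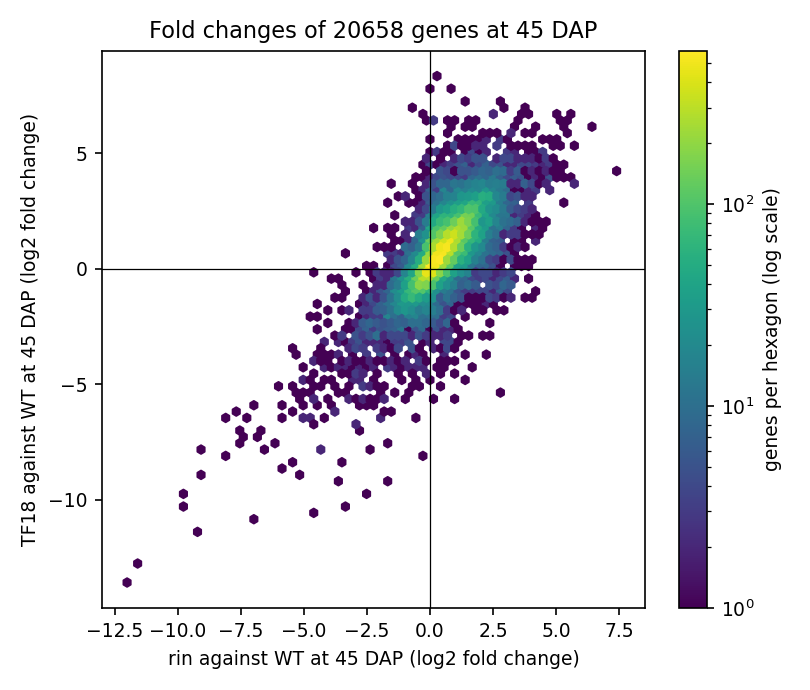
Log2 fold change against the wild type at 45 DAP in rin (x axis) and in TF18 (y axis) for 20658 genes, with color giving the number of genes per hexagon on a log scale. The fold changes have the same sign for 84.7% of genes, against 65.7% on average in simulated unchanged groups that share simulated controls. The observed correlation is 0.733, within the simulated range of -0.053 to 0.82.

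Tested directly at 45 DAP, TF18 had 2544 genes higher and 1065 lower than rin. Of 3887 genes higher than the wild type in TF18 and not in rin, 1559 were also higher in TF18 than in rin, and of 728 lower in TF18 and not in rin, 368 were also lower than in rin. In the opposite case 908 genes were higher in rin alone, 359 of them higher in rin than in TF18, and 157 were lower in rin alone, 52 of them lower in rin than in TF18. With TMM-type scaling TF18 had 1691 genes higher and 1490 lower than rin, and with quantile normalization 1515 and 1397. Across genes, on log2 values, TF18 libraries of 45 DAP had a mean correlation of 0.891 with the wild type of 35 DAP and 0.771 with the wild type of 45 DAP, and rin libraries of 45 DAP had 0.854 and 0.870.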

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

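The results here were picked out because the change from 35 to 45 DAP in rin or in TF18 differed from that in the wild type by limma's test of the difference itself, which was planned. The description of which other splits gave as many genes was chosen after the counts were seen.

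In rin, 10 genes rose in the wild type and fell in the mutant with a called difference, and 110 fell in the wild type and rose in the mutant. In TF18 these numbers were 2 and 46. The wild-type rises and falls they were drawn from numbered 1557 and 7072 on the deposited scale. With TMM-type scaling, 21 of 3651 wild-type rises fell in rin and 54 of 4926 wild-type falls rose there. In TF18 these were 2 and 32. The TMM-type counts do not require a called difference. Among the genes named by the rule, the log2 difference of the rin and wild-type changes was -11.60 for Solyc10g080210, -11.24 for Solyc08g066240, 6.38 for Solyc05g051850 and 5.98 for Solyc03g123830. For TF18 the log2 difference was -11.49 for Solyc10g080210, -11.51 for Solyc08g066240, 7.30 for Solyc03g005580, 2.67 for Solyc05g051850, 4.87 for Solyc03g123830 and 3.72 for Solyc07g007260. The value of Solyc03g005580 rests on libraries that differ widely, with 840 RPKM in TF18 replicate 1 of 35 DAP and 6.97 and 6.66 in the other two, and 516 RPKM in TF18 replicate 3 of 45 DAP and 3.15 and 1.19 in the other two.

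Other splits of the libraries were counted for these contrasts by exchanging genotypes within each age. For rin, 1 of 100 splits, the labelled one, gave as many as 5408 genes, but the highest of the others gave 5407. For TF18, 9 of 100 splits gave as many as the 8180 genes called, and the highest of the others gave 10239, so this count does not exclude chance for TF18. The splits are not all alike. Among those drawn for TF18, 11 kept the genotypes apart at 45 DAP and mixed them only at 35 DAP. These gave 7495 to 10239 genes, with 8 at or above the labelled split, and the highest of the rest gave 143. Among those drawn for rin, 9 did so, with 3940 to 5407 genes, and the highest of the rest gave 3. The large counts thus belong to splits that keep the labelled difference at 45 DAP, and the contrast draws mostly on the libraries of that age. The share of splits therefore cannot decide for rin or for TF18 whether the change over the interval differs beyond chance.

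For the genes called in the same direction in rin and TF18 at 45 DAP, 3 of 100 splits of the 9 libraries gave as many as 4986. The highest of the others gave 5814. Both of the other splits kept the wild-type libraries together and exchanged rin with TF18 libraries, and the highest of the rest gave 1. The count thus shows only that the wild-type libraries stand apart from those of rin and TF18. It cannot exclude chance for the overlap, since both comparisons share the wild-type libraries.

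The pairwise comparisons allow 10 splits of 6 libraries, too few for a share under 0.05, and in each 1 split, the labelled one, gave as many genes. The other splits mix the groups compared, so a real difference enters the spread within groups and lowers their counts by construction. The size of the gap between the counts is thus no measure of chance. The labelled and the highest other count were 8629 and 0 for the wild-type interval, 3374 and 2 for the rin interval, 147 and 4 for the TF18 interval, 19 and 15 for rin against the wild type at 35 DAP, 6051 and 7 for rin at 45 DAP, 1464 and 0 for TF18 at 35 DAP, 9601 and 0 for TF18 at 45 DAP, and 3609 and 0 for TF18 against rin. For TF18 at 35 DAP, where the replicate numbers may pair the libraries, 4 of the 10 splits part all 3 pairs as the labelled one does. The highest of the others among these gave 0. The rest keep pairs together and also gave 0.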

How the results depend on the processing

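Voom on recovered reads, thinning to equal depth and the replicate block within the groups compared were chosen after seeing the data, and the other settings were planned. Log2 fold changes of the named genes kept their direction and their call in all settings run. Of the counts, 222 values stayed within 1.5 times of the reported one and 66 did not, single left-out libraries apart. The replicate block changed no call of a named gene and moved no count by more. For TF18 and the wild type at 35 DAP, the 1 comparison where the numbers met the bound for pairing, it gave 526 higher and 796 lower. With only these groups in the fit it gave 593 and 1141. Those last counts differ from the reported 560 and 904 by the block and by the smaller fit together. Elsewhere the numbers did not meet the bound. Over all groups 14 of 45 same-numbered pairs correlated above 0.1 (lowest -0.382), and 5 of 18 libraries correlated best with their own number. Tests of the fixed gene lists (estimated correlation, block, fry) were not run, since no list was used. The cause of the shifts below was not tested, except that rescaling moves the median of all genes and a larger pseudocount shrinks the folds of low genes. Thinning moved no count by more than 1.5 times.

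With TMM-type scaling, higher and lower calls were 2832 and 1896 for rin against wild type at 45 DAP, 4760 and 3773 for TF18 against wild type at 45 DAP, 2157 and 1929 for the rin difference and 4426 and 3498 for the TF18 difference. The wild-type interval had 3651 higher, TF18 against rin 1691 higher, and the overlap at 45 DAP 2094 higher and 1636 lower. With quantile normalization the same counts were 1659 and 1367, 3254 and 2803, 1169 and 1192, and 2617 and 2888, with 3085 higher and 3196 lower for the wild-type interval, 1515 higher for TF18 against rin, an overlap of 1098 higher and 1078 lower, and 73 higher for the TF18 interval.

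With a pseudocount of 5, higher and lower calls were 982 and 933 for the rin interval and 312 and 469 for TF18 at 35 DAP. Lower calls were 3711 for the wild-type interval and 4 for rin at 35 DAP. Higher calls were 73 for the TF18 interval, 2477 for rin at 45 DAP, 4582 for TF18 at 45 DAP, 1100 for TF18 against rin, 2518 for the rin difference and 3947 for the TF18 difference. Higher in both at 45 DAP were 1844, shared interval rises were 373 in rin and 6 in TF18, and shared falls in rin were 832. With a pseudocount of 0.1, lower calls were 16 for the TF18 interval and 4 for rin at 35 DAP, and 18 rises were shared with TF18. With a filter at 5 RPKM, rin at 35 DAP had 7 higher and 4 lower, TF18 at 35 DAP 560 lower and the TF18 interval 19 lower.

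With library weights the TF18 interval had 646 higher and 211 lower, TF18 at 35 DAP 976 and 1612, TF18 against rin 1732 lower and rin at 35 DAP 12 lower, and the interval shared 92 rises and 114 falls with TF18. With only the groups compared, the TF18 interval had 66 higher and 8 lower, rin at 35 DAP 6 and 1, and the shared counts with TF18 were 6 rises and 1 fall. With voom on recovered reads the TF18 interval had 53 higher and 19 lower and shared 5 rises.

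Leaving out one library at a time gave 269 to 711 higher and 402 to 925 lower for TF18 at 35 DAP, 65 to 128 higher and 13 to 66 lower for the TF18 interval, and 5 to 20 shared rises and 5 to 41 shared falls in TF18. The lowest values for TF18 at 35 DAP came without TF18 replicate 2 of 35 DAP (269 and 402), which also gave 65 and 13 for the TF18 interval. Without wild-type replicate 1 of 35 DAP they were 313 and 475, without TF18 replicate 3 of 35 DAP the lower counts were 593 and 66, and without TF18 replicate 2 of 45 DAP the interval had 18 lower. The shallowest library, wild-type replicate 2 of 45 DAP, has 5740900 reads.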

Other observations

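The tests for the wild-type interval, the placement of the 8 Solyc05g genes in one prefix and at 45 DAP, and the shared rises and falls of TF18 were chosen after those results were seen. The left-out libraries for the Solyc05g genes and for TF18 at 35 DAP, and the set of 46 genes, were tested with the bound written before the value was seen.

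Some differences of TF18 were present at both ages, in comparisons that share no library. Higher than the wild type at both ages were 403 genes, where independent lists would share 225.6, and lower at both were 126, where they would share 55.9. Opposite directions at the 2 ages were called for 253 genes. Independent lists would give more, since 904 genes were lower at 35 DAP and 8323 of the 20658 tested were higher at 45 DAP. The lists at 35 DAP move with single libraries, as given above (269 higher and 402 lower without TF18 replicate 2 of 35 DAP, 313 and 475 without wild-type replicate 1, and 593 lower without TF18 replicate 3).

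The rin interval also held changes that were not called in the wild type. Of the genes that rose in rin, 871 were not called in the wild type, and for 468 of these the change was higher in rin by the test of the difference. Of those that fell, 173 were not called in the wild type, and for 41 the change was lower in rin. These counts are on the deposited scale. The genes were chosen on the same rin and wild-type libraries that enter the difference, so a called difference is partly favoured by the choice. Over all genes the difference was called higher for 4794 and lower for 614 as deposited, and for 2157 and 1929 with TMM-type scaling.

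A set of 46 genes was at least 8-fold higher, on the log2(RPKM + 1) scale, in TF18 replicate 1 of 35 DAP than in both other TF18 libraries of that age, and likewise in TF18 replicate 3 of 45 DAP. The 8 other choices of one TF18 library per age gave 0 such genes. In the wild type the highest number was 14, with replicate 2 at both ages, and in rin it was 2. Of the 46 genes, 26 fell in the wild type between the ages and 16 fell in rin. Solyc09g090150 had 974.6 RPKM in replicate 1 of 35 DAP and 2.70 and 0.91 in the other two, and 496.8 RPKM in replicate 3 of 45 DAP and 0.25 and 0.43 in the other two. A tissue held by some samples only may account for the set, and the falls of Solyc09g090150 and Solyc03g005580 in the wild type could then reflect tissue content and not a change within cells. This was not tested, as no tissue markers were used here. A gene list fixed in advance, whose entries could not be checked, places Solyc03g005580 among seed storage genes. The only value at hand, the ratio of 5.20 given below without the 46 genes, bears on another pattern. It leaves the question of tissue content open.

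The first pattern weighed is the excess of falls over rises in the wild type, 4.54 falls per rise as deposited. Shallower sequencing at 45 DAP is argued against, since the ratio was 4.44 with all libraries thinned to one depth, and so is the divergent wild-type replicate 2 of 45 DAP, without which it was 3.84. A few abundant genes taking reads from the rest stays open: the ratio was 1.35 after TMM-type scaling, but that scaling centres most genes and brings the ratio toward 1 by construction, so it cannot be told apart from a broad fall. The share of summed RPKM left by the 100 most abundant genes fell by 0.20 on the log2 scale, and the median gene by 0.58. The share left by all genes that rose, which were chosen on the same libraries, fell by 0.75. These sizes cannot be set against each other directly. Summed RPKM per wild-type library itself rose, from 1064939 to 1089065 at 35 DAP to 1245453 to 1285821 at 45 DAP. The median also depends on the pseudocount, and was -0.83 with 0.1 RPKM. A true broad fall in the ripening fruit stays open too, as relative values cannot show it.

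The second pattern is that 8 of the 19 genes that differed between rin and the wild type at 35 DAP share the prefix Solyc05g, where 1.26 were expected from 1365 of 20658 genes. Chance placement is argued against by a one-sided hypergeometric p of 0.000181 after multiplying by 13 prefixes, and one deciding library by the 6 to 8 such genes called when any of the 6 libraries was left out. A difference of the rin genotype that does not depend on age may account for it, as 6 of the 8 were called in the same direction at 45 DAP. TF18 at 35 DAP had 96 called genes with the prefix and 96.74 expected. An excess of a few genes could not be seen among its 1464 calls, so this decides nothing. The 11 other genes are no clear contrast, with 6 in the same direction at 45 DAP. Of the 8, 3 had reads in all 6 rin libraries and none in the other 12. A gene list fixed in advance, whose entries could not be checked, gives RIN itself an identifier with this prefix. Whether these genes lie in a stretch brought in with the rin mutation thus stays open and was not tested, since no positions were used here.

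The third pattern is that 414 of the 904 genes lower in TF18 than in the wild type at 35 DAP also fell in rin between 35 and 45 DAP, in comparisons that share no library, where independent lists would share 80. A single divergent TF18 library is argued against for the falls, since the ratio to independent lists was at least 4.78 without each TF18 library of 35 DAP. Without the set of 46 genes the ratio was 5.20, but only 9 of the 414 shared falls were in that set. Leaving it out could hardly move the ratio, so uneven tissue content stays open. The set also covers only genes that differ 8-fold. That TF18 fruit of 35 DAP stood further along the course seen in rin may fit the falls, but for the rises (80 shared, 41.9 expected) the ratio was 1.91, was 2.33 with TMM-type scaling (59 shared, 25.3 expected) and dropped to 1.42 without TF18 replicate 3, so it stays open. Changes in opposite directions were near what independent lists would share, with 57 genes higher in TF18 that fell in rin (49.5 expected) and 59 lower that rose (67.7 expected). Genes that fell in rin had a median log2 difference from the wild-type mean of -0.20, -0.28 and -0.64 in TF18 replicates 1, 2 and 3 of 35 DAP, and genes that rose in rin had -0.13, 0.05 and 0.39. For the rises replicate 1 thus goes the other way, replicate 2 lies near 0, and only replicate 3 shows both.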
